A study of Mus musculus with 6 samples.

How the data were processed

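Gene expression was measured in primary hepatocytes of C57BL/6 mice with an Affymetrix array, in 3 control samples and 3 samples stimulated with recombinant BMP2 at 50 ng/ml for 24 hours. Bone morphogenetic protein 2 (BMP2) is a secreted ligand that signals through SMAD transcription factors. The authors' deposited values were log2 expression values, 1 per probe set and sample, made by robust multi-array averaging (RMA) per the submitters' processing notes. The version of RMA, the array's probe grouping and any filter were not given in the sources used here. All values lay on steps of 1/1024 below 8 and of 1/512 from 8 upwards, so differences finer than these steps were not recorded. The medians of the 6 samples lay between 6.80 and 6.81, and the deposited log2 values were tested without further normalization.

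The table held 21115 probe sets, each numbered after a gene. A gene symbol was found for 20405 of them through the platform annotation, none had several, and 710 had no symbol here and were tested but not named. No symbol changed when the names were updated through the current gene table. An array holds no counts, so the precision rested on the 3 samples per group.

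BMP2 and control samples were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the default variance prior, two-sided), with Benjamini-Hochberg adjustment over all 21115 probe sets and a threshold of 0.05 on the adjusted p. Every adjusted p for a gene came from limma in this way, and every standard error (SE) came from the same model. Gene lists were tested with camera from the same package at a preset correlation between genes of 0.01, adjusted over the 32 lists. Each list was tested again with a correlation estimated from the data and with fry, which tests whether the genes of a list move, on balance, 1 way. Of 632 list genes 586 were measured. Of the 32 lists 6 held markers of other cell types of the liver and blood. The test, the lists, the rule for named genes and all alternatives except those described as added later were chosen before the data were examined.

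The rule for named genes took the 12 largest increases and the 12 largest decreases among genes past the threshold that moved the same way in all 3 pairs, leaving out predicted genes, small RNAs and probe sets without a symbol. It added 19 genes of the BMP pathway and of iron regulation whatever their result, and up to 4 members of each list with the smallest p. Some other list members are named, among them Alb, Cyp7a1, members called with the replicate block and abundant markers of other cell types, and these were chosen outside the rule after their values were seen.

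The study design states that the hepatocytes came from 3 mice, and the labels number the samples of each group from 1 to 3. Deviations from the group means correlated at 0.48, 0.58 and 0.61 between samples of the same number, and each sample correlated best with its own number, so the numbers were taken to pair the samples. The comparison without the pairing was the main test, and a model with the replicate number as a block was fitted beside it. Blocked values are given where they change the call of a gene or list described in the text, and blocked counts where they move by more than 1.5 times.

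The alternatives were a fixed or random replicate block, 2 filters on dim probe sets, an intensity trend in the variance prior with and without robust estimation, renewed quantile normalization, median centring, array weights, named probe sets alone, other thresholds, lists without shared members, and leaving out each sample in turn. The fits without 1 sample used no block, so 1 replicate number was then in 1 group alone. Differences between the mice can therefore add to or mask a change with BMP2 in those fits. Leaving out both samples of a replicate number, and combining the block with the intensity trend, with the omission of replicate 3 or with the other list tests, and an estimated correlation in the fits without 1 sample, were added after the data were seen.

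The scripts were tested on simulated data made from the control means of 21115 probe sets and the variances that limma estimated, with normal noise. In each set 50 genes were changed at each of 4 sizes. Over 10 simulated sets the model without the block recovered 68.2% of genes changed by 0.25 on the log2 scale, 92.2% of those changed by 0.5, 99.2% of those changed by 1 and 100% of those changed by 2, and 5.65% of its calls were false. The model with the block recovered 80.4%, 95.6%, 99.6% and 100% at the same sizes. Its share of false calls was 8.37% in the first simulated set. After that value was seen the number of sets was raised to 10, over which the mean share was 4.84%. Camera called the 1 list shifted by 0.3 on the log2 scale in every simulated set and 0.2 other lists on average. Genes were simulated independently of each other, so these sets could not show false list calls that arise from correlation between genes. The sets used for camera and for the model without the block held no differences between mice. Changed genes were drawn from all probe sets, of which 12236 had a mean under 7, and the full change was added to dim genes too. Real changes of dim genes are compressed, and the variance differs with the level. The recovered shares are therefore not the sensitivity for the expressed genes described below.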

Results

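The series measured how primary mouse hepatocytes respond to BMP2, a ligand that its title places in the control of iron homeostasis by liver vessels. There were 3 control samples and 3 samples stimulated with 50 ng/ml BMP2 for 24 hours, prepared from 3 mice. Expression values ranged from 6.35 to 14.0 on the log2 scale, and the medians of all samples lay between 6.80 and 6.81. The first principal component, with 62.3% of the variance, separated BMP2 from control samples. The second, with 21.5%, separated the samples of replicate 3 (6.45 in the control and 9.17 with BMP2) from the other samples (-4.83 to -2.94).

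The largest measured change was that of Hamp, which encodes the iron-regulatory hormone hepcidin. Its level rose from 7.86 ± 0.40 (SD, n = 3) in control to 13.48 ± 0.08 (SD, n = 3) in BMP2 samples, a 49.1-fold increase. Id1 and Atoh8, transcriptional regulators induced by BMP signals, rose 19.5-fold and 19.1-fold, from 7.39 ± 0.16 and 6.81 ± 0.06 (SD, n = 3) to 11.68 ± 0.06 and 11.07 ± 0.20 (SD, n = 3). Id3, another inhibitor of DNA binding, rose 6.58-fold, and Smad7, an inhibitory SMAD, rose 3.08-fold. Levels under 7 lay near the array's floor of 6.35, where changes are compressed, so changes from or to such levels were taken as lower bounds. Among the named genes that passed, these were the controls of Atoh8, Id3 (6.88), Smad9 (6.89) and Smad6 (6.90) and the BMP2 samples of Cdh17 (6.87), and the controls of Rdh7 (7.06), Nrn1 (7.01) and Ddit3 (7.04) lay just above. On the log2 scale the changes were 5.62 ± 0.21 for Hamp, 4.29 ± 0.09 for Id1, 4.26 ± 0.10 for Atoh8, 2.72 ± 0.09 for Id3 and 1.62 ± 0.07 for Smad7 (difference ± SE). The limma adjusted p was 0.0027 for Hamp, 0.00094 for Id1, 0.0011 for Atoh8, 0.0019 for Id3 and 0.0029 for Smad7, and these 5 genes stayed past the threshold with any 1 of the 6 samples left out.

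**Figure D1:**
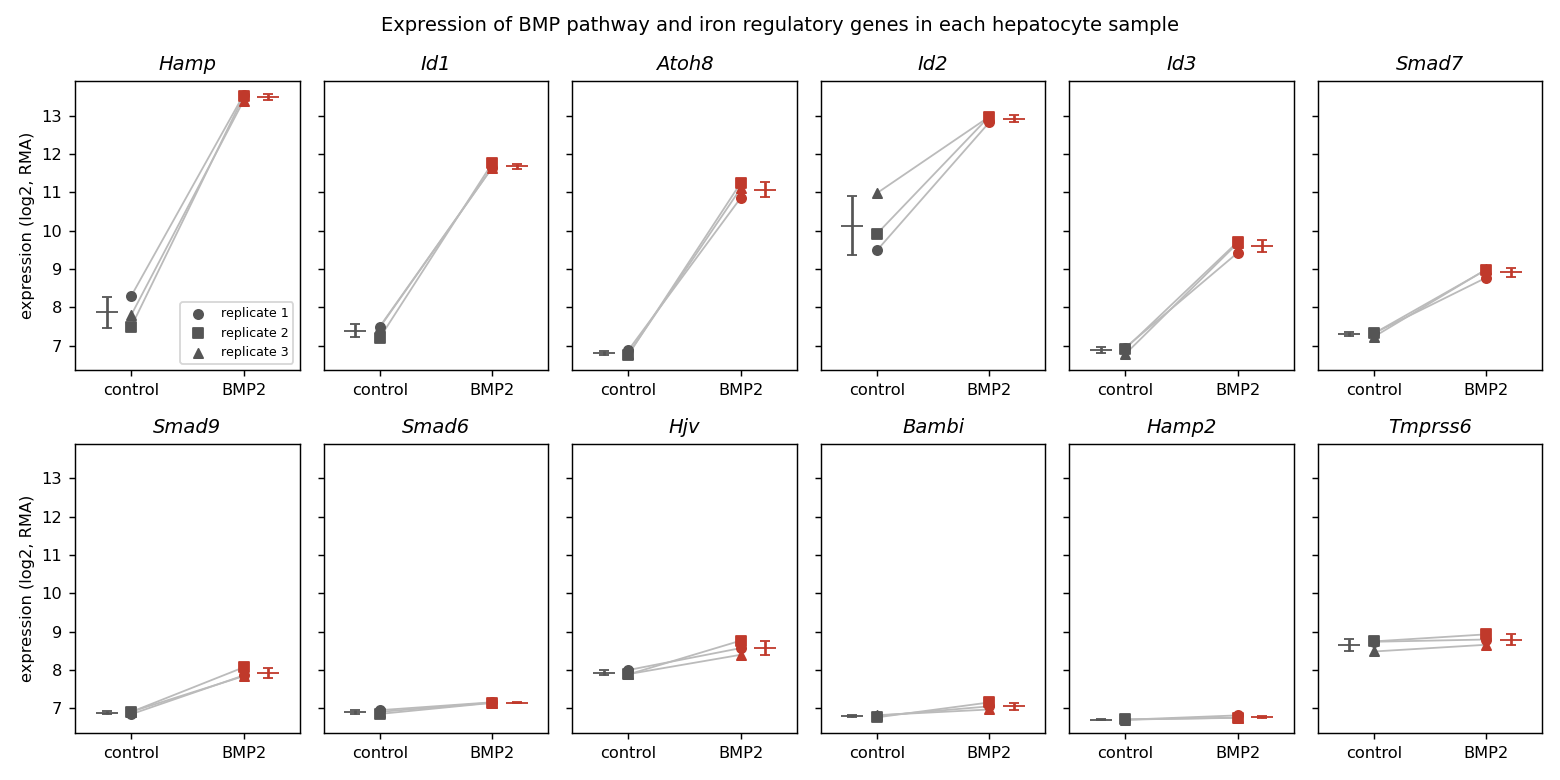
Expression (log2, RMA) of 12 BMP pathway and iron regulatory genes in each sample, with grey symbols for control, red symbols for BMP2, lines joining samples of the same replicate number, and bars for the mean ± SD of 3 samples. Hamp rose from 7.86 to 13.48, while Hamp2 (6.70 and 6.77) and Tmprss6 (8.65 and 8.79) did not pass the test.

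Over all genes, 251 of 21115 probe sets passed the limma threshold after Benjamini-Hochberg adjustment, 130 higher and 121 lower with BMP2. All 251 moved the same way in the 3 pairs. A difference large enough to pass makes this likely, so it is not separate support for the 251 calls. Of these, 21 rose and 9 fell by 2-fold or more, 104 changed by less than 1.2-fold, and 7 had no gene symbol here. With the replicate number as a block 702 probe sets passed, 355 higher and 347 lower, and 199 were shared with the 251. The count was 60 without control replicate 1, 53 without BMP2 replicate 1, 30 without control replicate 2, 76 without BMP2 replicate 2 and 83 without control replicate 3, against 223 without BMP2 replicate 3.

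**Figure D2:**
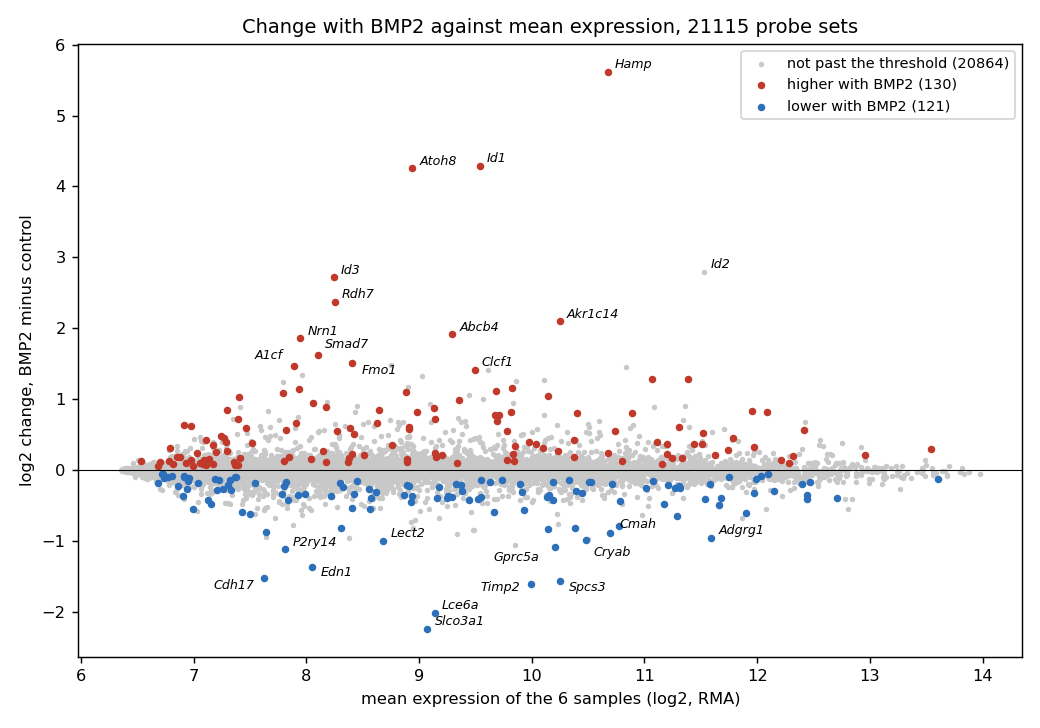
Change with BMP2 (log2, BMP2 minus control) against mean expression of the 6 samples (log2, RMA) for 21115 probe sets, with 130 higher in red, 121 lower in blue and the rest in grey. Hamp, Id1 and Atoh8 stand above 4 on the vertical axis, and Id2, at 2.80, is grey because its adjusted p was 0.054.

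Of 20 measured BMP-SMAD target genes 6 rose, none fell and 14 did not pass, and 9 rose when adjusted over the list alone. Beside Id1, Id3, Atoh8 and Smad7, the risers were Smad9, a BMP-responsive SMAD (1.03 ± 0.07, limma adjusted p = 0.0090), and Smad6, another inhibitory SMAD (0.24 ± 0.03, adjusted p = 0.030). Id2 differed by 2.80 ± 0.39 with an adjusted p of 0.054. Its control level in replicate 3 (10.98) lay above the other controls (9.48 and 9.92), and its adjusted p was 0.033 without control replicate 3. Bambi, a pseudoreceptor that dampens BMP signals, differed by 0.26 ± 0.05 (adjusted p = 0.10) and Id4 by 0.03 (adjusted p = 0.42). The control levels of Bambi (6.80) and Id4 (6.69) lay near the floor, where a change can be hidden. The list as a whole was shifted upwards (camera adjusted p = 2.7e-13), with an adjusted p = 0.057 with an estimated correlation. Smad9 had an adjusted p of 0.065 without control replicate 2, and Smad6 one of 0.126 without BMP2 replicate 1 and passed in 1 of the 6 fits with a sample left out.

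Of 17 measured genes of hepcidin regulation 5 rose, none fell and 12 did not pass, and 8 were higher and 1 lower when adjusted over the list alone. The risers were Hamp and the 4 BMP targets Id1, Atoh8, Smad7 and Smad6, which the BMP-SMAD list also holds. Hjv, the BMP co-receptor hemojuvelin, differed by 0.65 ± 0.10 (limma adjusted p = 0.065), with an adjusted p of 0.045 without BMP2 replicate 3. Bmp6, the other main BMP ligand of the liver, differed by -0.26 ± 0.07 (adjusted p = 0.24) and passed with the replicate block (adjusted p = 0.041). The paralogue Hamp2 differed by 0.07 ± 0.02 (adjusted p = 0.23), and Hfe (0.10), Tfr2 (0.12), Tmprss6 (0.14) and Bmp2 itself (-0.001) did not pass. Hamp2 (6.70 in control) and Bmp2 (6.57 in both groups) lay near the floor, so these values do not show that the 2 genes were unchanged. The list was shifted upwards (camera adjusted p = 2.4e-07), with an adjusted p = 0.26 with an estimated correlation.

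None of 28 measured genes of iron and haem handling passed in limma over all genes (2 higher and 3 lower when adjusted over the list alone), and the list was not shifted (camera adjusted p = 0.90). The iron exporter gene Slc40a1 stood at 10.84 in both groups (difference 0.003 ± 0.08) and the transferrin receptor gene Tfrc at 7.15 in both (0.01 ± 0.01). Hmox1, which encodes haem oxygenase, differed by 0.43 ± 0.08 (limma adjusted p = 0.095). With the replicate block Slc39a8 (-0.17, adjusted p = 0.048), Fbxl5 (-0.30, adjusted p = 0.017) and Lcn2 (-0.41, adjusted p = 0.025) were lower.

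Of 28 measured hepatocyte identity genes 3 rose, none fell and 25 did not pass, and 5 rose when adjusted over the list alone. The risers were 3 liver transcription factor genes, Hnf4a (0.82 ± 0.06, limma adjusted p = 0.0097), Prox1 (0.72 ± 0.09, adjusted p = 0.039) and Foxa3 (0.88 ± 0.12, adjusted p = 0.048). Ttr, the transthyretin gene, differed by 0.68 ± 0.11 (adjusted p = 0.073) and Fga, a fibrinogen gene, by 0.29 ± 0.08 (adjusted p = 0.22), and both passed with the replicate block (adjusted p = 0.017 for each), which made 5 members higher. Alb, the albumin gene, differed by -0.03 ± 0.03 (adjusted p = 0.85). Its control level of 13.81 lay near the highest value of any sample (14.0), so a rise may not have been measurable. The list was shifted upwards (camera adjusted p = 1.1e-05), with an adjusted p = 0.41 with an estimated correlation. Hnf4a passed in 4, Prox1 in 1 and Foxa3 in 0 of the 6 fits with a sample left out, with highest adjusted p of 0.067 without BMP2 replicate 1, 0.138 without BMP2 replicate 2 and 0.174 without BMP2 replicate 2.

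Of 22 measured genes of bile acid synthesis and transport 2 rose, 1 fell and 19 did not pass (3 higher and 1 lower when adjusted over the list alone). Abcb4, the canalicular phospholipid transporter, rose by 1.91 ± 0.24 (3.76-fold, limma adjusted p = 0.044), and Fgfr4, the receptor through which FGF15 represses bile acid synthesis, rose by 1.14 ± 0.04 (adjusted p = 0.0027). Amacr, a racemase of side-chain oxidation, fell by 0.35 on the log2 scale (SE 0.04, adjusted p = 0.039) and did not pass with the replicate block (adjusted p = 0.066). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, differed by 0.01 (adjusted p = 0.93). The median control level of the list was 6.71, near the floor, so a small difference of a dim member does not show that it was unchanged. The list was shifted upwards (camera adjusted p = 0.035), with an adjusted p = 0.55 with an estimated correlation, and this call was lost without control replicate 1 (0.091), BMP2 replicate 1 (0.096), BMP2 replicate 2 (0.167) or control replicate 3 (0.122). Fgfr4 passed with any 1 sample left out. Abcb4 and Amacr passed in 0 of 6 such fits (highest adjusted p 0.159 without BMP2 replicate 1 and 0.163 without control replicate 2). These fits used no replicate block. With all samples and the block Abcb4 passed (adjusted p = 0.010), with differences of 1.99, 1.84 and 1.90 in the 3 pairs.

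The cholesterol synthesis list was shifted upwards although 0 of its 19 measured members passed in limma over all genes (4 rose when adjusted over the list alone), with 17 of the 19 above 0. Its camera adjusted p was 5.0e-06, with an adjusted p = 0.41 with an estimated correlation. Hmgcs1 differed by 0.35 ± 0.06 (adjusted p = 0.080) and passed without BMP2 replicate 3 (adjusted p = 0.047), and Cyp51 differed by 0.11 ± 0.02 (adjusted p = 0.068). Hsd17b7 (0.21 ± 0.04) passed with the replicate block (adjusted p = 0.048). In the oxidative stress list Gclc, which encodes the catalytic subunit of glutathione synthesis, rose by 0.21 ± 0.02 (limma adjusted p = 0.017) and 17 of 18 members did not pass (5 rose when adjusted over the list alone). With the block Slc7a11, the cystine transporter gene, also rose (0.69, adjusted p = 0.017). Gclc passed in 2 of the 6 fits with a sample left out (highest adjusted p 0.086 without BMP2 replicate 2). The list was shifted upwards (camera adjusted p = 0.00014), with an adjusted p = 0.41 with an estimated correlation. Of 22 fatty acid oxidation genes Hadha, a subunit of the mitochondrial trifunctional protein, rose by 0.16 ± 0.02 (adjusted p = 0.046; 0.074 with the replicate block and 0.104 with an intensity trend) and 21 did not pass (6 higher and 1 lower when adjusted over the list alone). With the block Acadm (0.34, adjusted p = 0.037) rose and Vnn1 (-0.63, adjusted p = 0.010) fell. Hadha passed in 0 of the 6 fits with a sample left out (highest adjusted p 0.180 without control replicate 2). The fatty acid oxidation list was shifted upwards (camera adjusted p = 0.0067), with an adjusted p = 0.42 with an estimated correlation, and this call was lost without control replicate 1 (0.116) or BMP2 replicate 2 (0.0504).

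Of 28 measured cell cycle genes 26 lay below 0, with a median of -0.11, and none passed in limma over all genes (9 fell when adjusted over the list alone). The list's median control level was 7.10, just above the levels taken as near the floor, where changes are compressed. Mki67, the proliferation marker Ki-67, differed by -0.27 ± 0.04 (adjusted p = 0.054; 0.045 without BMP2 replicate 3) and Ccna2, cyclin A2, by -0.42 ± 0.07 (adjusted p = 0.084). Both passed with the replicate block (adjusted p = 0.048 and 0.040). The list was shifted downwards (camera adjusted p = 8.2e-11), with an adjusted p = 0.41 with an estimated correlation. Of 22 interferon response genes 21 lay below 0 and none passed (1 fell when adjusted over the list alone), with Oasl2 at -0.95 ± 0.16 (adjusted p = 0.081; 0.039 without control replicate 1) and Bst2 at -0.31 ± 0.07 (adjusted p = 0.14). That list was also shifted downwards (camera adjusted p = 1.1e-07), with an adjusted p = 0.39 with an estimated correlation.

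Of 30 measured mesenchymal and matrix genes 2 fell and 28 did not pass (3 higher and 8 lower when adjusted over the list alone). Fn1, fibronectin, fell by 0.12 (SE 0.02, limma adjusted p = 0.041; 0.066 with the replicate block) and Itgb1, integrin beta 1, fell by 0.11 (SE 0.01, adjusted p = 0.048; 0.209 with an intensity trend). Loxl2, a collagen cross-linking enzyme, differed by -0.76 ± 0.13 (adjusted p = 0.090) and passed with the replicate block (adjusted p = 0.020), which made 5 members lower and 2 higher. The list was shifted downwards (camera adjusted p = 0.0037), with an adjusted p = 0.45 with an estimated correlation, and not without BMP2 replicate 2 (adjusted p = 0.060). Fn1 and Itgb1 passed in 0 of the 6 fits with a sample left out (highest adjusted p 0.172 without control replicate 2 and 0.169 without BMP2 replicate 1).

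**Figure D3:**
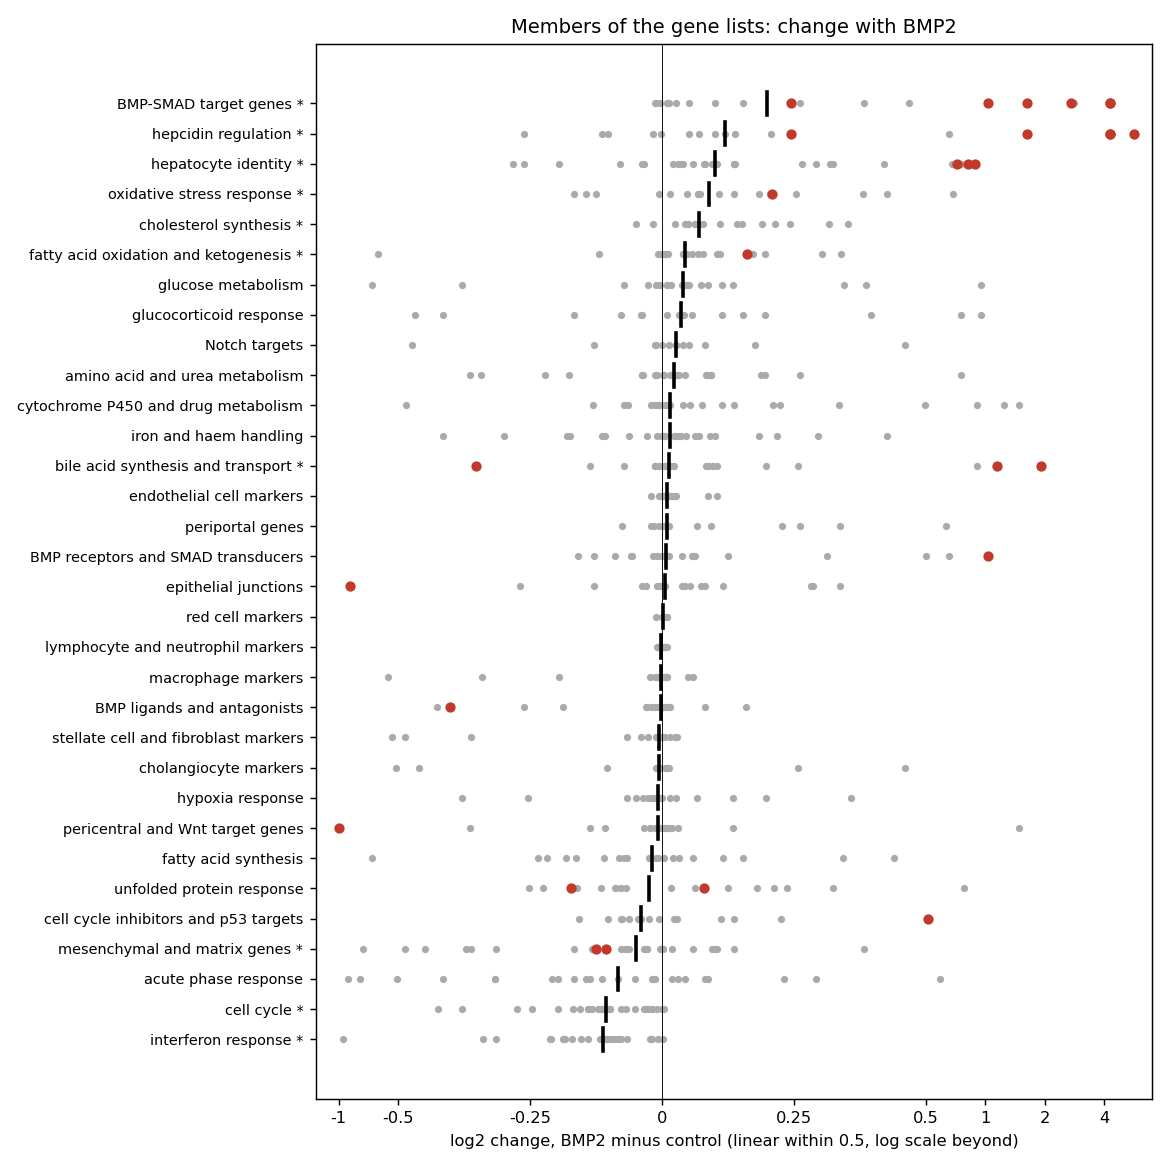
Change with BMP2 (log2, BMP2 minus control; linear within 0.5 and logarithmic beyond) of each member of the 32 gene lists, with black bars for list medians, red points for genes past the threshold over all genes, and an asterisk for the 10 lists shifted by camera with the preset correlation. The cell cycle median lies at -0.11 and the BMP-SMAD target median at 0.20, and 0 lists were shifted with an estimated correlation.

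Across the 32 lists 7 were shifted upwards and 3 downwards by camera, 0 with an estimated correlation, and fry called 2, the BMP-SMAD targets (adjusted p = 0.00023) and hepcidin regulation (adjusted p = 0.00037). With the replicate block 4 further lists were shifted: cytochrome P450 and drug metabolism (camera adjusted p = 0.014; 0.072 without the block), glucose metabolism (0.038; 0.13), acute phase response (0.00096; 0.072) and endothelial markers (0.040; 0.16). With the block and an estimated correlation these 4 had an adjusted p = 0.48, 0.64, 0.45 and 0.59. Without BMP2 replicate 3 the drug metabolism list also passed (0.0042), as it did without control replicate 2 (0.0083), and the acute phase list passed without control replicate 3 (0.00069) and without BMP2 replicate 1 (0.014). With an estimated correlation these fits gave an adjusted p = 0.47 and 0.50 for drug metabolism and 0.61 and 0.66 for the acute phase. Without BMP2 replicate 3 the acute phase list had a camera adjusted p of 0.66. Of its 25 genes 20 had their lowest mean in replicate 3 (list medians 10.99, 11.04 and 10.42 in replicates 1, 2 and 3). Leaving out control replicate 3 keeps that replicate in the BMP2 group alone, so its low levels can add to a fall. Another split of the 6 samples into 3 and 3 gave this list a camera p of 1.4e-07, against 0.026 for the real one. Endothelial markers passed without BMP2 replicate 1 (0.026), with an adjusted p = 0.66 with an estimated correlation. None of the 25 drug metabolism genes and none of the 25 acute phase genes passed in limma without the block (2 higher and 0 lower, and 0 and 0, when adjusted over the list alone). With the block 4 drug metabolism genes were higher and 1 lower, and 2 acute phase genes higher and 4 lower. Of these, Cyp1a2 (1.48, adjusted p = 0.030) and Cyp3a11 (1.25, adjusted p = 0.040) rose, while Crp, C-reactive protein (-0.78, adjusted p = 0.010), and Lbp, which binds lipopolysaccharide (-0.90, adjusted p = 0.017), fell.

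Among the other large increases Rdh7, a retinol dehydrogenase, rose 5.19-fold (2.38 ± 0.28, limma adjusted p = 0.038) and Akr1c14, a hydroxysteroid dehydrogenase, 4.27-fold (2.10 ± 0.13, adjusted p = 0.0082). Clcf1, a cytokine of the interleukin-6 family, rose 2.67-fold (1.42 ± 0.05, adjusted p = 0.0019). Nrn1 (3.63-fold, adjusted p = 0.020), the flavin monooxygenase gene Fmo1 (2.84-fold, adjusted p = 0.046) and A1cf, a factor of apolipoprotein B RNA editing (2.76-fold, adjusted p = 0.033), also rose. Clcf1 passed with any 1 sample left out. Of the 6 such fits Akr1c14 passed in 4, Nrn1 in 2, and Rdh7, Fmo1 and A1cf in 1. The highest adjusted p of Rdh7 was 0.143, without BMP2 replicate 1. Without control replicate 2 the highest values were 0.062 for Akr1c14, 0.0997 for Nrn1, 0.179 for Fmo1 and 0.149 for A1cf.

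The largest decrease was that of Slco3a1, an organic anion transporter, which fell by 2.24 on the log2 scale (SE 0.19, 4.73-fold, limma adjusted p = 0.018). Lce6a fell by 2.01 (SE 0.12, adjusted p = 0.0077), Timp2, a metalloproteinase inhibitor, fell by 1.61 (SE 0.12, adjusted p = 0.013), and Spcs3, a subunit of the signal peptidase complex, fell by 1.56 (SE 0.05, adjusted p = 0.0015). Cdh17 (-1.52), Edn1, which encodes endothelin-1 (-1.36), P2ry14 (-1.12), Gprc5a (-1.08), Lect2 (-1.0), the small heat shock protein gene Cryab (-0.99), Adgrg1 (-0.95) and Cmah (-0.89) also fell, with limma adjusted p between 0.0054 (Cryab) and 0.048 (Edn1). All of these genes also passed with the replicate block, Lect2 with an adjusted p of 0.010 and differences of -1.01, -0.98 and -1.01 in the pairs. Spcs3 and Cryab passed with any 1 sample left out, in fits without the block. Of those 6 fits Lce6a and Cdh17 passed in 5, and Slco3a1, Timp2 and P2ry14 in 2. Edn1, Gprc5a, Adgrg1 and Cmah passed in 1 and Lect2 in 0. The highest adjusted p of the others was 0.096 for Slco3a1, 0.0502 for Lce6a, 0.081 for Timp2, 0.063 for Cdh17, 0.107 for Gprc5a, 0.131 for Lect2 and 0.095 for Adgrg1 without BMP2 replicate 1, and 0.175 for Edn1, 0.123 for P2ry14 and 0.118 for Cmah without control replicate 2.

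Of 22 BMP receptors and SMAD transducers only Smad9 rose without the replicate block (2 higher when adjusted over the list alone; camera adjusted p = 0.15), and 3 rose with it, the others being the TGF-beta receptor genes Tgfbr1 (0.50, adjusted p = 0.040) and Tgfbr2 (0.31, adjusted p = 0.028). Of 23 BMP ligands and antagonists only Fst, the activin antagonist follistatin, fell (by 0.40, SE 0.05, limma adjusted p = 0.035; 0 higher and 2 lower when adjusted over the list alone; camera adjusted p = 0.15) without the block, and with it Bmp4 (-0.43, adjusted p = 0.022) and Bmp6 were also lower. Gadd45a, a growth arrest gene, rose by 0.51 ± 0.07 (adjusted p = 0.048) and was the 1 change without the block among 17 cell cycle inhibitors and p53 targets (camera adjusted p = 0.53), a list whose median (-0.04) and mean (0.02) differ in sign. With the block Gadd45b was also lower (-0.16, adjusted p = 0.022). Among 20 genes of the unfolded protein response Ddit3 rose by 0.08 (adjusted p = 0.048; 0.070 with the replicate block and 0.139 with an intensity trend) and Pdia4 fell by 0.17 (adjusted p = 0.0079; 0.124 with an intensity trend), and the median (-0.03) and mean (0.03) also differ in sign (camera adjusted p = 0.80). With the block 3 genes of that list rose, among them Herpud1 (0.78, adjusted p = 0.030), and 2 fell. Cldn2, a claudin, fell by 0.88 (SE 0.09, adjusted p = 0.032) and 18 of 19 epithelial junction genes did not pass (median 0.01, mean -0.002, camera adjusted p = 0.89), while 2 of them, among them the E-cadherin gene Cdh1 (0.34, adjusted p = 0.021), rose with the block. Of 18 pericentral and Wnt target genes Lect2 fell and 17 did not pass (camera adjusted p = 0.18), against 2 higher and 3 lower with the block, among them Glul, glutamine synthetase (-0.36, adjusted p = 0.046). Adjusted over the list alone, 2 higher and 1 lower, 4 and 4, 1 and 3, and 0 and 1 members of these 4 lists passed. The highest adjusted p with a sample left out was 0.126 for Fst, 0.146 for Cldn2 and 0.058 for Pdia4 without control replicate 2, 0.172 for Gadd45a without BMP2 replicate 2, and 0.168 for Ddit3 without BMP2 replicate 1.

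No member passed in limma over all genes among 20 genes of fatty acid synthesis (camera adjusted p = 0.69), 20 of glucose metabolism (0.13), 25 of amino acid and urea metabolism (0.35), 15 periportal genes (0.15), 13 Notch targets (0.30), 18 genes of the hypoxia response (0.89) and 16 of the glucocorticoid response (0.11). Adjusted over the list alone, 1, 4, 5, 0, 0, 5 and 6 members of these lists passed. Without BMP2 replicate 3 the periportal (0.039) and glucocorticoid (0.020) lists passed by camera, as did the BMP ligands and antagonists (0.049). With an estimated correlation these fits gave an adjusted p = 0.50, 0.38 and 0.57. With the replicate block the numbers higher and lower were 3 and 3, 3 and 1, 0 and 1, 2 and 0, 2 and 1, 1 and 0, and 1 and 1. Among these, the fatty acid synthesis gene Dgat2 rose by 0.44 (adjusted p = 0.017), the glycolytic gene Pklr fell by 0.68 (adjusted p = 0.024) and the Notch ligand gene Jag1 fell by 0.47 (adjusted p = 0.042).

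The median control level of markers of other cell types was 6.71 for 20 endothelial, 6.62 for 20 macrophage, 6.65 for 20 stellate cell and fibroblast, 6.70 for 14 cholangiocyte, 6.54 for 19 lymphocyte and neutrophil and 6.55 for 5 red cell markers, against 9.15 for hepatocyte identity. No member of these lists passed in limma over all genes (0, 2, 1, 4, 0 and 0 when adjusted over the list alone), and none of the 6 lists was shifted without the block (camera adjusted p = 0.16, 0.69, 0.072, 0.30, 0.72 and 0.89). The stellate list passed without control replicate 2 (0.038) and without BMP2 replicate 3 (0.025), with an adjusted p = 0.69 and 0.57 with an estimated correlation. The most abundant macrophage and stellate markers, Cd14 (8.23) and Ecm1 (8.92), differed by -0.56 ± 0.08 (adjusted p = 0.051) and -0.53 ± 0.08 (adjusted p = 0.058), and Ecm1 passed with the replicate block (adjusted p = 0.030). With an intensity trend Cd14 (adjusted p = 0.0086), Ecm1 (0.014) and the cholangiocyte marker Krt19 (0.019) passed as lower and the macrophage marker Lyz2 (0.05, adjusted p = 0.030) as higher. Of 14 cholangiocyte markers 4 lay above the third quartile of all values (7.96): Cldn4 (11.9), Sox9 (9.94), Bicc1 (9.78) and Krt19 (8.77). Krt19 differed by -0.51 ± 0.08 (adjusted p = 0.073; 0.0496 without BMP2 replicate 3) and Cldn4 by 0.26 ± 0.18 (adjusted p = 0.72). With the replicate block Bicc1 fell by 0.46 (adjusted p = 0.017) and Sox9 rose by 0.46 (adjusted p = 0.039), and the endothelial marker Emcn rose by 0.09 (adjusted p = 0.048).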

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

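The settings that leave out both samples of a replicate number, those that combine the replicate block with another choice, and the estimated correlation without 1 sample, were chosen after the data were seen. Against 251 changed probe sets (130 higher, 121 lower) limma gave 702 (355, 347) with the replicate block, 700 (358, 342) with a random replicate block, 449 (226, 223) above the median level, 438 (217, 221) with an intensity trend, 468 (228, 240) with trend and robust estimation, 403 (201, 202) with array weights, and 1278 (607, 671) with block and trend. It gave 567 (294, 273) at an adjusted p under 0.1, 68 (46, 22) with a change of at least 1.5-fold and 22 (14, 8) with treat against 1.2-fold. Leaving out 1 sample gave 30 to 223 changed, 13 to 125 higher and 17 to 98 lower, and 7 to 15 shifted lists. Without both samples of replicate 1, 2 or 3 limma gave 9 (7, 2), 2 (1, 1) and 114 (65, 49), and with the block and without replicate 3 it gave 0 (0, 0), with 3739 at an unadjusted p under 0.05 and 1 residual degree of freedom. Fewer samples enter these fits, and for the other settings the cause was not tested. The first-quartile filter (363), quantile normalization (283), median centring (224) and named probe sets alone (255) stayed within 1.5 times of 251. Of the lists, 10 were shifted in the main test, 16 without both samples of replicate 3, 0 by camera with an estimated correlation with or without the block or with any 1 sample left out, 2 by fry and 8 by fry with the block. Lists without shared members gave 11, BMP-SMAD targets (adjusted p = 2.8e-05) and hepcidin regulation (0.025) among them. With the block 52 of the 251 calls were lost and 503 gained. These totals include the gene calls named with their blocked values and those of other list members and probe sets. The settings of filter, variance prior and normalization ended and added calls. Among the genes taken by the naming rule 40 passed in the main test, and 9 of these passed in all 6 fits with 1 sample left out. Of the 144 genes taken by that rule 31 gained and 4 lost a call with the intensity trend. Those described in the text that gained one were Id2 (adjusted p = 0.0059), Cd14 (0.0086), Mki67 (0.012), Hjv (0.012), Ttr (0.013), Ecm1 (0.014), Oasl2 (0.014), Vnn1 (0.018), Dgat2 (0.018), Krt19 (0.019), Herpud1 (0.019), Ccna2 (0.020), Loxl2 (0.021), Bambi (0.026), Lyz2 (0.030), Hmox1 (0.033), Hmgcs1 (0.041) and Pklr (0.043). All of these but Lyz2 and Pklr also passed above the median level, and array weights gave 17 gained calls. The stellate list passed above the median level (0.039) and the acute phase list with median centring (0.043). Calls lost were those of 8 genes and 2 lists described in the text. With trend and robust estimation Pdia4 (adjusted p = 0.087), Hadha (0.104), Itgb1 (0.261), Ddit3 (0.123) and Fn1 (0.115) did not pass, and the first 4 did not with the trend alone. Median centring ended the calls of Hadha (0.059), Itgb1 (0.072), Ddit3 (0.067), Fn1 (0.061) and Foxa3 (0.0503), and quantile normalization those of Itgb1 (0.0507), Ddit3 (0.0513), Fn1 (0.132), Fst (0.0510) and Gadd45a (0.059). Above the median level Itgb1 (0.076), Ddit3 (0.132), Fn1 (0.054) and the bile acid and fatty acid oxidation lists (0.056 for each) did not pass, and above the first quartile Ddit3 (0.060) did not. Many dim genes lie near the array's floor of 6.35, where changes are compressed: 27 of 12236 probe sets with a mean under 7 passed.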

Other observations

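The comparison of the 3 mice, and the tests of other cells, of differences between the mice, of the signal peptidase complex and of neighbouring genes, were chosen after the results were seen. Samples of replicate 3 had first been tested against replicates 1 and 2, because they stood apart on the second principal component. That test was set aside after its result was seen, since it picked samples by a measured outcome, and both tests of a question about hepatocyte identity genes in replicate 3 were dropped with it, 1 that had argued against other cells and 1 that had left a single array undecided. A test over all 3 mice took its place.

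With BMP2 in the model, 6 probe sets differed between the 3 mice in limma with Benjamini-Hochberg adjustment (3126 at an unadjusted p under 0.05), 5 of them named. Nt5e, which encodes an ecto-nucleotidase, had means of 8.5, 9.14 and 9.65 in replicates 1, 2 and 3, and Mest had 7.16, 7.52 and 7.90. Itih4, an inter-alpha-trypsin inhibitor gene, stood at 11.84 in replicate 1 and 11.89 in replicate 2, against 11.08 and 10.91 in the control and BMP2 samples of replicate 3. Gadd45b stood at 10.68, 10.79 and 11.18, and Gstm7, a glutathione transferase gene, at 7.95, 8.05 and 7.60 in the 3 replicates (adjusted p = 0.049 for each of the 5 genes). Of the 6 probe sets 4 also changed with BMP2 in the model with the replicate block, among them Nt5e, higher by 0.93 in BMP2 samples and in 3 of 3 pairs (adjusted p = 0.010). Cells of another type in a preparation stay open: the highest median of their marker lists in any replicate was 6.73 (endothelial), below the third quartile of all values (7.96), but 8 single markers lay above that quartile in the controls, at levels that would hide a small share. Their means in replicates 1, 2 and 3 were, for example, 8.03, 7.88 and 7.95 for Cd14, 8.73, 8.54 and 8.68 for Ecm1, 8.54, 8.45 and 8.54 for Krt19, 9.43, 9.50 and 9.73 for Bicc1 and 12.18, 12.13 and 11.74 for Cldn4. Handling of the preparations and biological differences between the mice were not tested.

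Hepatocyte identity genes were shifted upwards with BMP2 by camera with the preset correlation. Fewer cells of another type in the BMP2 wells stays open: the highest control median of such cells' marker lists was 6.71 (most abundant members Gata4 at 7.61, Cd14 at 8.23, Ecm1 at 8.92, Cldn4 at 11.9, Ccl5 at 6.84 and Slc4a1 at 6.79), but of the 8 markers above the third quartile 6 were lower in all 3 pairs, among them Cd14 (-0.56), Ecm1 (-0.53, adjusted p = 0.030 with the block), Krt19 (-0.51) and Bicc1 (-0.46, adjusted p = 0.017 with the block), of which the first 3 passed with an intensity trend, while Sox9 (0.46) and Cldn4 (0.26) were higher, and 5 stellate and 2 cholangiocyte markers are also in another list. If the numbers pair the samples, each mouse is in both groups, and a fixed difference between the mice cancels by design. The list's median within the pairs was 0.126, 0.124 and 0.081, with 24, 22 and 23 of 28 members above 0. These values show that the shift did not rest on 1 pair. If the numbers do not pair the samples, the medians decide nothing about the mice. Of the 28 members 19 had their lowest mean in replicate 3. Another split of the samples gave the list a camera p of 2.4e-06 against 2.0e-06 for the real one. An effect of BMP2 is 1 open explanation, and the shift had an adjusted p = 0.41 with an estimated correlation.

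Spcs3 fell by 1.56 on the log2 scale in BMP2 samples, and in 3 of 3 pairs. A joint fall of the transcripts of the signal peptidase complex is argued against by 3 other subunit genes. These were Spcs1 (-0.05), Spcs2 (-0.12, adjusted p = 0.47) and Sec11a (-0.03), while Sec11c (6.94 in control) was too dim to count. The array measured transcripts only, so the amount of the complex as protein was not tested. A single array does not account for the fall, which was at least 1.51 in size (-1.51) with any 1 of the 6 samples left out. Transcripts of the flanking genes read by its probes stay open, since Vegfc (6.72 in control) and Asb5 (6.67) lay near the floor, where levels decide nothing. A response of Spcs3 itself to BMP2 is another open explanation, and probes that cross-react with an unrelated transcript were not tested.

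The 6 samples can be split into 3 and 3 in 10 ways, too few for a share under 0.05. In limma, 1 of the 10 splits gave as many changed probe sets as the real one, the real one itself (251, against a highest other count of 0, with 202 to 1660 at an unadjusted p under 0.05 in the others). With the replicate block the real split gave 702 and each of the other 3 splits that part all pairs gave 0. Of the list counts, 3 of the 10 splits shifted at least as many lists as the real split (10), with a highest other count of 15 for the split that set control 1 with both samples of replicate 3, which follows the replicate numbers in part. For 3 lists shifted in the real split another split gave a smaller camera p: mesenchymal and matrix genes (0.00065 against 0.00092), fatty acid oxidation (0.00062 against 0.0019) and bile acid synthesis and transport (0.00030 against 0.011). Among the other shifted lists the smallest p of another split was 6.2e-09 against 5.1e-12 for cell cycle and 7.0e-06 against 9.9e-09 for interferon response. It was 1.9e-05 against 7.8e-07 for cholesterol synthesis, 5.0e-05 against 3.1e-05 for oxidative stress and 2.4e-06 against 2.0e-06 for hepatocyte identity. For BMP-SMAD targets it was 0.00052 against 8.5e-15, and for hepcidin regulation 0.030 against 3.1e-08. Splits that mixed the groups thus also gave small camera p.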
